A study of Mus musculus with 8 samples.

How the data were processed

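RNA was measured as poly(A) RNA-seq in 8 libraries of mouse bone marrow-derived macrophages, 1 untreated and 7 stimulated for 4 h. Per the submitters' processing notes, reads were aligned to mm9 with TopHat 1.3.1 and quantified with Cufflinks 1.2.1 and Cuffdiff 1.2.1; options, read counts and strandedness are not given in the sources used here, so overlapping and antisense genes cannot be separated. The authors deposited, for each stimulus, a table of FPKM with lower and upper confidence bounds for the stimulated and the untreated library, per the file headers, and their level is not stated there. A second table per stimulus holds the authors' Cuffdiff comparison with its q-value and a yes or no call, per the file headers; the highest q-value among the called genes was below 0.05. Each of the 14 tables has 36806 gene lines, of which 336 to 388 per stimulus had a status other than OK in either library and were left out. FPKM divides by transcript length and by a library total, so a few very abundant transcripts lower the values of all others. The log2 ratio column of the second table holds placeholder values and was not used.

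Gene symbols were found for 31840 of 36806 identifiers in GENCODE release 21 for mouse, which also gave transcript length, GC content and biotype; 4966 had none. Coordinates are those of the deposited tables in mm9, counted from 1, and span the locus Cufflinks assembled, which can hold several genes. No coordinate of another build was used. Near-identical genes, such as the Gbp family, Serpina3f and Serpina3g, Tgtp1 and Tgtp2, Hspa1a and Hspa1b and the H2 genes, can share reads, and their separate values are uncertain.

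The 8 libraries were grouped by their labels, with 1 library per group, so no replicate test was possible and no p-value was computed. A gene was counted when its status was OK, its FPKM was at least 1 in either library, and log2 of (stimulated FPKM + 1) over (untreated FPKM + 1) was at least 1 in size. A fold on this scale understates the change of genes of low FPKM. No fold is given against a library that lists a gene at 0. The genes named for each stimulus were the 10 highest and 6 lowest in log2 change that passed this rule and were also called in the authors' table, plus the 2 to 4 members of each gene list that changed most, the receptor genes of each agent, and 5 genes in each direction for 4 pairs of stimuli. The 29 gene lists, the size rule, the naming rule and the other alternatives than those said to be added were fixed before the data were examined, and 4 further lists were written later. For each list the members with at least 1 FPKM in either library were counted in each direction, and the median was placed among 10000 random lists of the same size matched on expression decile, as a description of these libraries. A list with fewer than 3 measured members was given no median. Some genes that these rules name are not reported here.

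The untreated values of all 7 tables differ by 1 factor per table, so the tables were joined by it. Each stimulus was also compared with the median of the other 6 stimulated libraries. Correlations and overlaps were set beside 20 draws of simulated unchanged libraries, with noise drawn from the difference of TNFa and IL1b within 10 expression deciles. The alternatives tried were a pseudocount of 0.1, a floor of 5 FPKM, no floor, centring on the median gene, the authors' call, list members held by no other list, and, added after the data were seen, protein-coding genes alone and the other 6 stimulated libraries as the reference. On simulated data for IL4 against untreated, with 12589 genes, the counting rule recovered 48 of 50 genes changed 2.5-fold. It recovered 50 of 50 at 4, 8 and 16-fold, and 145 unchanged genes (1.17%) passed. Noise of 1 library was added to the stimulated values only, and the changed genes had at least 5 FPKM untreated. A real comparison holds the noise of both libraries, so this share is too low for it. With noise in both, simulated unchanged libraries had 211 higher genes each. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.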

Results

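Poly(A) RNA was sequenced from mouse bone marrow-derived macrophages, which are grown from C57BL/6 marrow in medium conditioned by the fibroblast line L929, a source of the growth factor CSF1. Differentiation lasted 7 days. 1 culture was left untreated and 7 were stimulated for 4 h with a single agent: interferon gamma (IFNg, 100 ng/ml), interleukin 4 (IL4, 10 ng/ml), tumour necrosis factor (TNFa, 10 ng/ml), transforming growth factor beta (TGFb1, 1 ng/ml), interleukin 1 beta (IL1b, 10 ng/ml), the mycoplasmal lipopeptide MALP2 (1 ng/ml), a ligand of the receptor pair Tlr2 and Tlr6, or unmethylated CpG DNA (100 nM), a ligand of Tlr9. Each group held 1 library, so no difference has a replicate check. A pair of values written as 1 against another gives the stimulated and then the untreated library of the same table. The bounds in parentheses are the authors' confidence bounds on FPKM within a library, and folds are on the FPKM + 1 scale. The highest and lowest genes named for each stimulus are those among the genes that the authors also called significant. Short RNA genes without that call went further, such as Snord42b after MALP2 (log2 change -10.2). Absolute depth is unknown, because the tables give FPKM and no counts. From the low values, 1 read was worth 2.04 times as much FPKM in the IFNg library as in the untreated one, and between 1.05 and 1.44 times as much in the other 6, so the IFNg library was the shallowest relative to it. Among genes at 1 FPKM or more in both libraries the median log2 change lay between -0.10 (CpG) and -0.071 (TGFb1). With changes centred on that median, the share of higher genes among those at least 2-fold apart went from between 43.9% and 46.2% to between 50.9% and 54.4%. Higher genes then outnumbered lower ones in all 7 comparisons instead of the reverse.

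Receptor transcripts for 6 of the 7 agents stood at 9.62 FPKM or more in the untreated macrophages: Ifngr1 at 119 FPKM (55.9 to 183) and Ifngr2 at 103, Il4ra at 106 and Il2rg at 129, Tnfrsf1a at 97.8 and Tnfrsf1b at 244, Tgfbr1 at 11.4 and Tgfbr2 at 57.2, Tlr2 at 71.9 and Tlr6 at 9.62, and Tlr9 at 51.7 FPKM. The IL1 receptor was the exception, with Il1r1 at 0.294 FPKM (0.0718 to 0.516) and its partner Il1rap at 1.95 FPKM (0.666 to 3.23). Transcripts of the 30 receptor and signalling genes on this list had a median log2 change of -0.44 to 0.65 over the 7 comparisons. Il4ra was higher after IFNg (848 against 100.3 FPKM) and CpG (787 against 104 FPKM), and in the joined tables it was 106 FPKM untreated, 302 after IL4, 387 after MALP2 and 91.1 to 141 FPKM in the other 3. Tlr9 was 5.64 to 11.7 FPKM after 6 of the agents, at least 2-fold lower than untreated, and 28.7 FPKM after IFNg.

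Markers of other cell types were looked up in every library. Of 11 erythroid genes none reached 1 FPKM in any library, and of 16 T and NK cell genes only Cd4 and Lck did. Of 14 B and plasma cell genes, Ighm, Blnk, Cd79b and Cd22 were above 1 FPKM, with Ighm at 124 FPKM untreated and 15.1 to 29.7 FPKM after stimulation, and the list median was -1.98 to -1.32 over the 7 comparisons and -0.30 to 0.27 against the other 6 stimulated libraries. The B cell genes Cd79a (0.0348 FPKM) and Ms4a1 (0.0156 FPKM) were near 0 in the untreated library. Of 15 neutrophil genes S100a8 was the highest in every library, at 119 FPKM untreated. The median level of the 15 genes was 0.509 FPKM (TGFb1) to 1.81 FPKM (untreated). Their median log2 change ran from -0.95 to -0.029, lowest after IL4. Stromal genes stood apart in the IFNg library: Col1a2 was 23.2 FPKM untreated, 49.2 FPKM after IFNg and 22.7 to 26 FPKM in the other 6, and the list median was 0.97 after IFNg against 0.061 to 0.16 in the others. Levels set across stimuli in this way come from tables scaled separately by the authors and joined here through the untreated values.

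**Figure D1:**
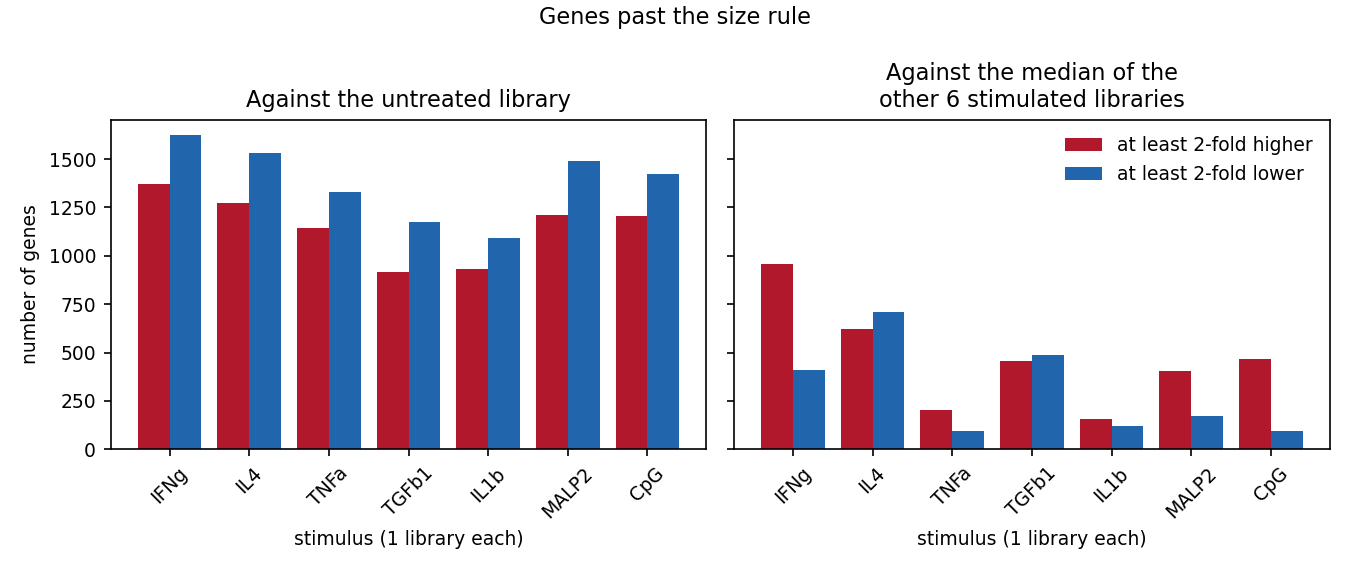
Number of genes (vertical axis) at least 2-fold higher (red) or lower (blue) for each stimulus, 1 library each, against the untreated library (left) and against the median of the other 6 stimulated libraries (right). Against the untreated library the counts run from 918 to 1623, and against the other stimulated libraries from 94 to 960.

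IFNg, the cytokine of classical macrophage activation, was compared with no treatment. The chemokine Cxcl9 (ENSMUSG00000029417, mm9 chromosome 5, 92750357 to 92757105) had the highest change among called genes. It was at 0.129 FPKM (0.0535 to 0.205) in the untreated library and 655 FPKM (175 to 1135) in the IFNg library, 581-fold on the FPKM + 1 scale. The uridine phosphorylase Upp1 was 462-fold higher (869 against 0.881 FPKM) and the protease inhibitors Serpina3g and Serpina3f 423-fold and 156-fold higher. Cxcl10, a ligand of the same receptor as Cxcl9, was 7163 against 25.5 FPKM, the guanylate-binding protein gene Gbp2 4318 against 22.9 FPKM, the immunity-related GTPase Iigp1 235 against 0.492 FPKM, and Socs1, a feedback inhibitor of cytokine receptors, 259.6 against 0.814 FPKM. AA467197 was 197-fold higher. Acod1, the itaconate-producing enzyme, was at 6.05 FPKM (2.21 to 9.9) in the untreated library and 2626 FPKM (0 to 5280.5) in the IFNg library, with bounds that overlap.

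Genes of the IFNg-activated group, among them the guanylate-binding proteins and immunity-related GTPases, were higher together: 30 of 31 measured members passed 2-fold upward and 0 downward, with a median log2 change of 4.59, percentile 100 among 10000 random lists matched on expression. Of 35 genes known from type I interferon responses 28 were higher (median 1.61), led by Ifi47 (1103 against 58.6 FPKM), Ifi205 (394 against 30.6 FPKM), Mx1 (169 against 17.5 FPKM) and Oasl1 (155 against 16.3 FPKM). In the MHC class I pathway 9 of 19 members were higher (median 0.84), with the peptide transporter Tap1 at 531 against 77.6 FPKM and the class I transactivator Nlrc5 at 119.9 against 18.4 FPKM. In the class II list 5 of 10 were higher (median 1.02), including the transactivator Ciita (20.7 against 2.92 FPKM), while H2-Ab1 (111 against 41.5 FPKM) and Cd74 (473 against 190.3 FPKM) were not called by the authors. Inflammatory cytokine and mediator genes had a median of 1.82 with 17 of 21 higher, among them Tnf (578 against 6.72 FPKM), Il1rn (1662 against 23.1 FPKM) and Ptgs2 (78.4 against 0.629 FPKM). Chemokine genes had a median of 2.35 (13 of 18 higher), including Ccl7 (136-fold) and Ccl12 (122-fold). NF-kB target and feedback genes had a median of 1.80 (34 of 40), led by Cd40 (999.9 against 14.1 FPKM). The stromal marker median beside these groups was 0.97.

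Cell cycle genes were lower after IFNg, 17 of 31 by at least 2-fold (median -1.17, percentile 0), such as Ccnb2 (2.88 against 14.9 FPKM), Bub1b (2.53 against 12.8 FPKM) and Aurkb (1.79 against 9.57 FPKM), whereas Ccnd1, the cyclin of growth factor entry into the cycle, was 37.4-fold higher. Sterol synthesis genes had a median of -0.70 at percentile 0.13 and -1.40 against the other stimulated libraries, with Mvd at 3.9 against 31.4 FPKM and Dhcr7 at 5.27 against 31.8 FPKM, while glycolysis and hypoxia genes were higher (18 of 23, median 1.3), led by the glucose transporter Slc2a1 (284 against 16.3 FPKM). The lowest called genes were Cxcr4, a chemokine receptor (7.32 against 303 FPKM), Slc26a11 (26.3-fold lower), Tmem273 (24.8-fold lower), Arhgap19 (24.3-fold lower) and Tcp11l2 (23.9-fold lower). Lmbr1 was listed at 57.2 FPKM (0 to 227) in the untreated library and 0.581 FPKM (0.143 to 1.02) in the IFNg library, an interval that runs from 0 and leaves its value open here and in the IL4, TNFa, IL1b and MALP2 comparisons, where it was also among the lowest. In the IFNg comparison 12813 genes could be compared, of which 1373 were at least 2-fold higher and 1623 at least 2-fold lower than in the untreated library. Of these, 969 and 1073 were also called significant in the authors' deposited table, which calls 2716 genes in all and compares these 2 libraries, not the conditions. The call lowered the lower genes by more than 1.5 times. Beside that, 960 genes were at least 2-fold higher and 409 at least 2-fold lower than the median of the other 6 stimulated libraries. Of the above genes the change against the other 6 was 8.93 for Cxcl9 but -0.51 for Arhgap19 and -0.54 for Tcp11l2. With IFNg set against the other 6 stimulated libraries, the median was 4.50 for IFNg-activated genes (29 higher and 0 lower of 31), 2.27 for interferon response genes (33 higher and 0 lower of 35) and 1.19 for class I genes (12 higher and 0 lower of 19). For IFNg on that reference it was 0.83 for class II genes (3 higher and 0 lower of 9), 0.74 for cytokine genes (10 higher and 2 lower of 22) and 0.16 for chemokine genes (8 higher and 7 lower of 19). Again for IFNg, it was 0.43 for NF-kB genes (10 higher and 2 lower of 39), -0.41 for cell cycle genes (1 higher and 2 lower of 29) and 0.22 for glycolysis genes (4 higher and 1 lower of 23).

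IL4, the cytokine of alternative macrophage activation, had its highest change among called genes in Arg1, the arginase gene (ENSMUSG00000019987, mm9 chromosome 10, 24635014 to 24647276). Arg1 was at 0.0357 FPKM (0 to 0.0768) in the untreated library and 1837 FPKM (593 to 3081) in the IL4 library, a 1775-fold difference on the FPKM + 1 scale. The arginine transporter gene Slc7a2 was 114-fold higher (205 against 0.799 FPKM), the adhesion molecule Cdh1 83.6 against 0.0353 FPKM, the vascular growth factor receptor Flt1 99.7 against 0.293 FPKM, and Tmem26 61.1 against 0.101 FPKM. The monocyte chemokines Ccl7 (1026 against 4.71 FPKM) and Ccl2 (714 against 9.45 FPKM) and the eosinophil chemokine Ccl24 (74.3 against 0.629 FPKM) were higher, as were Socs1 (50.1-fold) and the glycosyltransferase gene B3gnt7 (42.9-fold). Of 35 measured genes on the alternative activation list, 29 were at least 2-fold higher and 1 lower, with a median of 2.69 (percentile 100) and 2.01 against the other 6 stimulated libraries. The same list had a median of 1.40 at percentile 100 after IFNg, with 21 of 34 higher, and 0.93 against the other stimulated libraries. With the other 5 agents its medians were 0.41 to 0.91, all above the random lists, and -0.48 to 0.25 on that reference.

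Genes of interferon responses were lower in the IL4 library. 29 of 35 passed 2-fold downward and 0 upward, with a median of -1.71 (percentile 0). Ifit3 was 74.3 FPKM (31.4 to 117) in the untreated library and 5.72 FPKM (2.15 to 9.29) in the IL4 library, Ifit2 3.1 against 31.5 FPKM, Oasl1 1.51 against 18 FPKM and Cmpk2 3.91 against 30.1 FPKM. The IFNg-activated list had a median of -1.12 with 14 of 25 lower, among them Irgm1 (31.2 against 113 FPKM), and the MHC class I list a median of -1.02 with 11 of 19 lower, among them Nlrc5 (4.39 against 20.3 FPKM) and Tap1 (28.1 against 85.5 FPKM). Class II genes had a median of -0.40 at percentile 15.2. NF-kB genes had a median of -0.22 at percentile 18.2 against the untreated library and -2.19 against the other stimulated libraries, with Tnfaip2 lower (29.5 against 251 FPKM), Traf1 lower (1.48 against 10.4 FPKM) and the kinase gene Ripk2 higher (42.7 against 6.02 FPKM). Inflammatory cytokine genes had a median of -0.23 at percentile 24.6, with Il15 lower (1 against 10.7 FPKM) and Edn1, the endothelin gene, higher (7.61 against 0.0701 FPKM), and chemokine genes a median of 0.073 at percentile 83.1. Against the other 6 stimulated libraries these medians were -1.69 for cytokine genes and -1.65 for chemokine genes, with 11 of 17 chemokine genes lower. The neutrophil marker median was -0.95 at percentile 0.06 in the same library.

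Cell cycle genes had a median of -0.78 after IL4, with 10 of 31 lower, while glycolysis and hypoxia genes had a median of 0.34 (-1.0 against the other stimulated libraries) and 4 of 23 higher, and Myc was 28.2-fold higher (127 against 3.55 FPKM). Among the lowest called genes were Ptafr, the receptor of platelet-activating factor (6.59 against 193 FPKM, with bounds of 2.68 to 10.5 and 74.4 to 312), Gpr162 (20.0-fold lower), Cxcr4 (18.1-fold lower) and Fnip2 (17.3-fold lower). In the IL4 comparison 12908 genes could be compared, of which 1273 were at least 2-fold higher and 1530 at least 2-fold lower than in the untreated library. Of these, 876 and 1051 were also called significant in the authors' deposited table, which calls 2770 genes in all and compares these 2 libraries, not the conditions. In addition, 624 genes were at least 2-fold higher and 710 at least 2-fold lower than the median of the other 6 stimulated libraries. Ptafr was -3.78 and Arg1 7.98 on that scale, but Cxcr4 was -0.33 and Gpr162 -0.49. With IL4 set against the other 6 stimulated libraries, the median was -1.51 for interferon response genes (0 higher and 30 lower of 35), -1.35 for IFNg-activated genes (2 higher and 18 lower of 26) and -0.97 for class I genes (0 higher and 8 lower of 19). For IL4 on that reference it was -0.26 for class II genes (1 higher and 3 lower of 9) and -0.16 for cell cycle genes (0 higher and 0 lower of 29).

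TNFa, an inflammatory cytokine, was compared with no treatment. The fatty acid receptor gene Gpr84 (ENSMUSG00000063234, mm9 chromosome 15, 103138667 to 103140869) was highest among called genes. It was at 3.94 FPKM (1.49 to 6.39) in the untreated library and 725 FPKM (282 to 1168) in the TNFa library, 147-fold. Acod1 was 998 against 6.41 FPKM, the prostaglandin E synthase gene Ptges 231 against 1.06 FPKM, the scavenger receptor Olr1 61.2 against 0.0341 FPKM, the caveolin gene Cav1 81.3 against 0.828 FPKM, and the lectin receptor Clec4e 979.9 against 22.6 FPKM. Slc7a2, Trem1, Il1b and the cholesterol hydroxylase gene Ch25h were 39.1-fold, 34.6-fold, 32-fold and 31.8-fold higher. Chemokine genes had a median of 2.37 (percentile 100), with 15 of 18 higher, including the neutrophil chemokines Cxcl3 (35.3 against 0.256 FPKM) and Cxcl2 (75.8 against 2.05 FPKM) and the T cell chemokine Ccl22 (36.5 against 0.732 FPKM). NF-kB genes had a median of 1.48 (25 of 39 higher), with the adhesion molecule Vcam1 at 20.4 against 0.525 FPKM and the superoxide dismutase Sod2 at 230.4 against 18.4 FPKM.

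Inflammatory cytokine genes had a median of 0.99 after TNFa (9 of 19 higher), among them Saa3, an acute phase protein gene (188 against 10.2 FPKM), and glycolysis and hypoxia genes 1.27 (16 of 23), with Egln3 at 12.4 against 0.709 FPKM. Interferon response genes had a median of 0.021 at percentile 82.4 against the untreated library and 0.72 against the other stimulated libraries. 6 members were higher, such as Ifi203 (80.1 against 21 FPKM), and 1 lower. The IFNg-activated list had a median of 0.59, the class I list 0.00074, and the class II list -0.097 (0.31 against the other stimulated libraries). Cell cycle genes had a median of -0.67 at percentile 0.02. The lowest called genes were Arhgap19 (2.07 against 69.6 FPKM, with bounds of 0.864 to 3.28 and 29.6 to 109), Slc46a3 (21.2-fold lower), Slc26a11 (20.0-fold lower), Tcp11l2 (17.5-fold lower) and the Ras activator Rasgrp3 (16.8-fold lower). In the TNFa comparison 12825 genes could be compared, of which 1144 were at least 2-fold higher and 1332 at least 2-fold lower than in the untreated library. Of these, 821 and 921 were also called significant in the authors' deposited table, which calls 2570 genes in all and compares these 2 libraries, not the conditions. By contrast, 203 genes were at least 2-fold higher and 94 at least 2-fold lower than the median of the other 6 stimulated libraries. Ptges was 3.97 and Ccl22 3.01 on that scale, whereas Ch25h was -0.042 and Tcp11l2 -0.058, and the cytokine and NF-kB medians turned to -0.014 and -0.012. With TNFa set against the other 6 stimulated libraries, the median was 0.44 for chemokine genes (5 higher and 2 lower of 18), 0.54 for IFNg-activated genes (2 higher and 2 lower of 27) and 0.33 for class I genes (0 higher and 0 lower of 19). For TNFa on that reference it was -0.078 for cell cycle genes (0 higher and 0 lower of 29) and 0.30 for glycolysis genes (1 higher and 0 lower of 23).

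TGFb1 acts through SMAD transcription factors, and the highest called gene was Pmepa1, a feedback inhibitor of that pathway (ENSMUSG00000038400, mm9 chromosome 2, 173049959 to 173102034). It was at 1.51 FPKM (0.849 to 2.17) in the untreated library and 143 FPKM (108 to 179) in the TGFb1 library, 57.4-fold. The chemokine Cxcl14 was 188 against 3.38 FPKM, the transcription regulator Id1 72.3 against 1.11 FPKM, Olr1 25.8 against 0.0352 FPKM, the transglutaminase gene Tgm2 1378 against 54.7 FPKM, Gpr84 114 against 4.05 FPKM, the FK506-binding protein gene Fkbp5 217 against 9.78 FPKM, AA467197 81.9 against 3.27 FPKM, and Spsb1 33.6 against 0.783 FPKM. The small nucleolar RNA gene Snora16a was listed at 0 FPKM in the untreated library and 24.6 FPKM (4.32 to 45) after TGFb1. Of 34 measured SMAD pathway and target genes, 20 were higher and 5 lower, with a median of 1.34 at percentile 100 and 0.52 against the other 6 stimulated libraries, including the platelet-derived growth factor genes Pdgfb (77 against 6.44 FPKM) and Pdgfa (173 against 18.6 FPKM). The same list had medians of 0.25 to 0.80 with the other 6 agents (-0.31 to 0.16 against the other stimulated libraries), and Pmepa1 was 30.7 to 75.6 FPKM in them.

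Interferon response genes were lower in the TGFb1 library, 18 of 35 by at least 2-fold (median -1.02 at percentile 0), with the transcription factor Irf7 at 242 FPKM (189.9 to 294) in the untreated library and 49.8 FPKM (39 to 60.6) in the TGFb1 library, Oas3 at 15.3 against 71.1 FPKM and Oasl2 at 55.1 against 232 FPKM. The IFNg-activated list had a median of -0.83 (8 of 24 lower, such as Irf1, 25 against 82.6 FPKM), the class I list -0.90 (8 of 19 lower), and the class II list -0.32, in which Ciita was lower (0.307 against 3.19 FPKM). In the same library the neutrophil marker median was -0.67 at percentile 0.43 and the dendritic marker median -0.71 at percentile 1.72. NF-kB genes had a median of 0.10 against the untreated library and -2.05 against the other stimulated libraries, with Tnfaip2 (34.1 against 248 FPKM) and Cd83 (11.5 against 59.9 FPKM) lower. Cytokine genes had a median of -0.40 at percentile 4.14 and chemokine genes 0.30 at percentile 96.8, with Ccl4 lower (13 against 115 FPKM) and Ccl2 higher (51.3 against 9.35 FPKM). Against the other 6 stimulated libraries the cytokine median was -1.50 and the chemokine median turned to -2.58, with 15 of 17 chemokine genes lower. Sterol synthesis genes had a median of 0.86 (6 of 19 higher), with squalene epoxidase Sqle at 108 against 20.6 FPKM, and the fractalkine receptor gene Cx3cr1 was 116 against 20.2 FPKM.

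The lowest called genes after TGFb1 were Rassf4 (14.7 against 269 FPKM, with bounds of 10.1 to 19.3 and 163 to 375), Lrrc14b (16.2-fold lower), Calhm6 (15.4-fold lower), the iron exporter Slc40a1 (15.2-fold lower), Gpr162 (14.2-fold lower) and the chemokine Ccl3 (9.17 against 138 FPKM). In the TGFb1 comparison 12847 genes could be compared, of which 918 were at least 2-fold higher and 1175 at least 2-fold lower than in the untreated library. Of these, 654 and 845 were also called significant in the authors' deposited table, which calls 2535 genes in all and compares these 2 libraries, not the conditions. On the other reference, 457 genes were at least 2-fold higher and 487 at least 2-fold lower than the median of the other 6 stimulated libraries. There Rassf4 was -3.09 and Ccl3 -3.99, while Lrrc14b was 0.029. Of the highest genes after TGFb1, Fkbp5 was 2.61, Snora16a 2.04, Cxcl14 1.93, Spsb1 1.82 and Pmepa1 1.63. The rest were Tgm2 at 0.35, Id1 at 0.19, AA467197 at -0.041, Olr1 at -0.069 and Gpr84 at -2.33. With TGFb1 set against the other 6 stimulated libraries, the median was -1.05 for interferon response genes (0 higher and 20 lower of 35), -1.0 for IFNg-activated genes (0 higher and 13 lower of 26) and -0.99 for class I genes (0 higher and 7 lower of 19). For TGFb1 on that reference it was -0.54 for class II genes (0 higher and 1 lower of 9) and 0.47 for sterol synthesis genes (1 higher and 0 lower of 19).

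IL1b, an inflammatory cytokine, was compared with no treatment. Gpr84 (444 against 3.99 FPKM, with bounds of 212 to 676 and 1.7 to 6.27), Acod1 (312 against 6.49 FPKM), Id1 (70.5 against 1.1 FPKM), Il1b itself (163 against 3.99 FPKM), Cxcl2 (95.1 against 2.07 FPKM) and Cxcl14 (119 against 3.32 FPKM) were highest among called genes. They were followed by Ccl7 (23.5-fold), Tnf (22.9-fold), the amplifying receptor Trem1 (21-fold) and Olr1 (20.4-fold). Chemokine genes had a median of 1.56 at percentile 100 with 12 of 17 higher, such as Cxcl1 (30.9 against 0.683 FPKM). Cytokine genes had a median of 1.03 at percentile 100 with 10 of 19 higher. NF-kB genes had a median of 1.40 at percentile 100 with 27 of 40, such as Nfkbie (91.3 against 9.25 FPKM), an inhibitor of NF-kB, and Tnip3 (56.5 against 4.11 FPKM). Sterol synthesis genes included 9 of 19 that were 2-fold higher (median 0.91, 0.73 against the other stimulated libraries), including Sqle (115 against 20.2 FPKM) and Cyp51 (112 against 26.7 FPKM). Interferon response genes had a median of -0.45 at percentile 0.05 with 5 of 35 lower, and class I genes -0.54. The IFNg-activated list had a median of -0.32 at percentile 4.28, with 5 of 26 higher, such as Cxcl10 (231 against 27.3 FPKM), and 0 lower. Class II genes had a median of -0.24. The lowest called genes were the cholesterol exporter Abcg1 (5.49 against 100.1 FPKM), Lrrc14b (15.6-fold lower), Tcp11l2 (15.5-fold lower), Cbx8, whose bounds overlap, and Rnf144b (12.6-fold lower). In the IL1b comparison 12768 genes could be compared, of which 931 were at least 2-fold higher and 1094 at least 2-fold lower than in the untreated library. Of these, 681 and 841 were also called significant in the authors' deposited table, which calls 2448 genes in all and compares these 2 libraries, not the conditions. Beside this, 154 genes were at least 2-fold higher and 122 at least 2-fold lower than the median of the other 6 stimulated libraries. Of these, 75 and 22 also passed the rule in that direction against the untreated library. Against the other 6, Gpr84 was 0.14 and Il1b 0.77, and the cytokine and NF-kB medians turned to -0.28 and -0.14. With IL1b set against the other 6 stimulated libraries, the median was 0.011 for chemokine genes (4 higher and 4 lower of 18), -0.38 for interferon response genes (0 higher and 1 lower of 35) and -0.50 for IFNg-activated genes (0 higher and 7 lower of 26). For IL1b on that reference it was -0.50 for class I genes (0 higher and 1 lower of 19) and -0.49 for class II genes (0 higher and 1 lower of 9).

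MALP2 and CpG engage different Toll-like receptors, at the cell surface and in endosomes. After MALP2 the cytokine gene Il1b (ENSMUSG00000027398, mm9 chromosome 2, 129190306 to 129201484) was highest among called genes. It was at 3.87 FPKM (1.24 to 6.49) in the untreated library and 3018 FPKM (626 to 5409) in the MALP2 library, 620.1-fold. Saa3 was 4717 against 9.98 FPKM, Gpr84 921 against 3.87 FPKM, Acod1 1368 against 6.3 FPKM and Ptges 373 against 1.04 FPKM. The neutrophil chemokines Cxcl2, Cxcl1 and Cxcl3 were 176-fold, 90.5-fold and 65-fold higher, Tnf 82.1-fold and Il1a 77.3-fold. Chemokine genes had a median of 3.87 at percentile 100 (16 of 17 higher), cytokine genes 3.23 at percentile 100 (18 of 23), and NF-kB genes 2.0 at percentile 100 (33 of 40), led by Socs3 (592 against 8.76 FPKM) and Nfkbiz (118 against 4.51 FPKM). Glycolysis and hypoxia genes had a median of 1.83 (18 of 24), with the lactate transporter Slc16a3 at 503 against 27.5 FPKM. Interferon response genes had a median of -0.32 at percentile 0.92, 7 of 35 lower such as Ifit2 (6.97 against 29.8 FPKM), and the IFNg-activated list 0.13, in which Nos2, the inducible nitric oxide synthase, was higher (40.9 against 0.053 FPKM). The class I and class II lists had medians of -0.13 and 0.048 (0.31 and 0.19 against the other stimulated libraries), and sterol synthesis genes 0.68. Cell cycle genes had a median of -0.56, and 0.032 against the other stimulated libraries.

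Cxcr4 was the lowest called gene after MALP2, at 315 FPKM (195 to 435) in the untreated library and 4.16 FPKM (2.27 to 6.05) in the MALP2 library, 61.3-fold lower. It was followed by Slc26a11 (27.3-fold lower), Rasgrp3 (22.6-fold lower), Arhgap19 (22.4-fold lower) and Tmem154 (21.7-fold lower). In the MALP2 comparison 12722 genes could be compared, of which 1212 were at least 2-fold higher and 1491 at least 2-fold lower than in the untreated library. Of these, 806 and 1018 were also called significant in the authors' deposited table, which calls 2529 genes in all and compares these 2 libraries, not the conditions. In turn, 405 genes were at least 2-fold higher and 174 at least 2-fold lower than the median of the other 6 stimulated libraries. Saa3 was 7.16, Il1b 5.01 and Cxcr4 -2.34 on that scale, and Arhgap19 was -0.37. Asking for the authors' call thus lowered the higher genes by more than 1.5 times. With MALP2 set against the other 6 stimulated libraries, the median was 1.56 for chemokine genes (10 higher and 1 lower of 17), 1.99 for cytokine genes (17 higher and 1 lower of 23) and 0.44 for NF-kB genes (13 higher and 0 lower of 39). For MALP2 on that reference it was 0.69 for glycolysis genes (9 higher and 0 lower of 24), -0.27 for interferon response genes (0 higher and 4 lower of 35) and 0.15 for IFNg-activated genes (3 higher and 2 lower of 26). Again for MALP2, it was 0.25 for sterol synthesis genes (0 higher and 0 lower of 19).

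After CpG, Il1b was also highest among called genes (3075 against 3.86 FPKM, with bounds of 379 to 5771 and 1.21 to 6.52), and Saa3 was 5353 against 9.97 FPKM. Acod1 and Il1a were 159.7-fold and 151-fold higher, Nos2 was 121 against 0.0529 FPKM, the collagenase gene Mmp13 272 against 1.54 FPKM, the cyclooxygenase gene Ptgs2 166 against 0.654 FPKM, and Gpr84, Cxcl2 and Cxcl3 149.5-fold, 109-fold and 93.9-fold higher. Cytokine genes had a median of 3.86 at percentile 100 (19 of 23 higher), chemokine genes 3.89 at percentile 100 (16 of 17), such as Ccl5 (779.8 against 22.8 FPKM), and NF-kB genes 2.36 at percentile 100 (35 of 40), such as Tnfaip3 (229 against 6.53 FPKM), the deubiquitinase that restrains NF-kB. Immediate early and stress genes had a median of 0.99, with the phosphatase genes Dusp2 (61.2 against 1.39 FPKM) and Dusp1 (137 against 7.74 FPKM) among the higher ones, and the glycolytic regulator Pfkfb3 was 424 against 22.8 FPKM (list median 1.71). Interferon response genes had a median of 0.11 at percentile 87.5, the IFNg-activated list 0.51, the class I list 0.037 and the class II list -0.19. Cell cycle and sterol synthesis genes had medians of -0.67 and 0.084, and the second turned to -0.52 against the other stimulated libraries. The lowest called genes were Cxcr4 (11.3 against 315 FPKM), Arhgap19, Slc26a11, Rasgrp3, Slc46a3 and Tcp11l2, which were 18.6-fold to 23.4-fold lower apart from Cxcr4 (25.7-fold). In the CpG comparison 12769 genes could be compared, of which 1204 were at least 2-fold higher and 1425 at least 2-fold lower than in the untreated library. Of these, 843 and 989 were also called significant in the authors' deposited table, which calls 2641 genes in all and compares these 2 libraries, not the conditions. For the second reference, 465 genes were at least 2-fold higher and 96 at least 2-fold lower than the median of the other 6 stimulated libraries. Nos2 was 5.87 on that scale, and Tcp11l2 -0.18. With CpG set against the other 6 stimulated libraries, the median was 2.42 for cytokine genes (18 higher and 0 lower of 23), 1.51 for chemokine genes (9 higher and 0 lower of 17) and 0.59 for NF-kB genes (16 higher and 0 lower of 39). For CpG on that reference it was 0.33 for immediate early genes (6 higher and 0 lower of 30), 0.59 for glycolysis genes (9 higher and 0 lower of 24) and 0.70 for interferon response genes (3 higher and 0 lower of 35). Again for CpG, it was 0.69 for IFNg-activated genes (9 higher and 0 lower of 26), 0.36 for class I genes (0 higher and 0 lower of 19) and -0.078 for class II genes (0 higher and 0 lower of 9). Last for CpG, it was -0.063 for cell cycle genes (0 higher and 1 lower of 29).

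**Figure D2:**
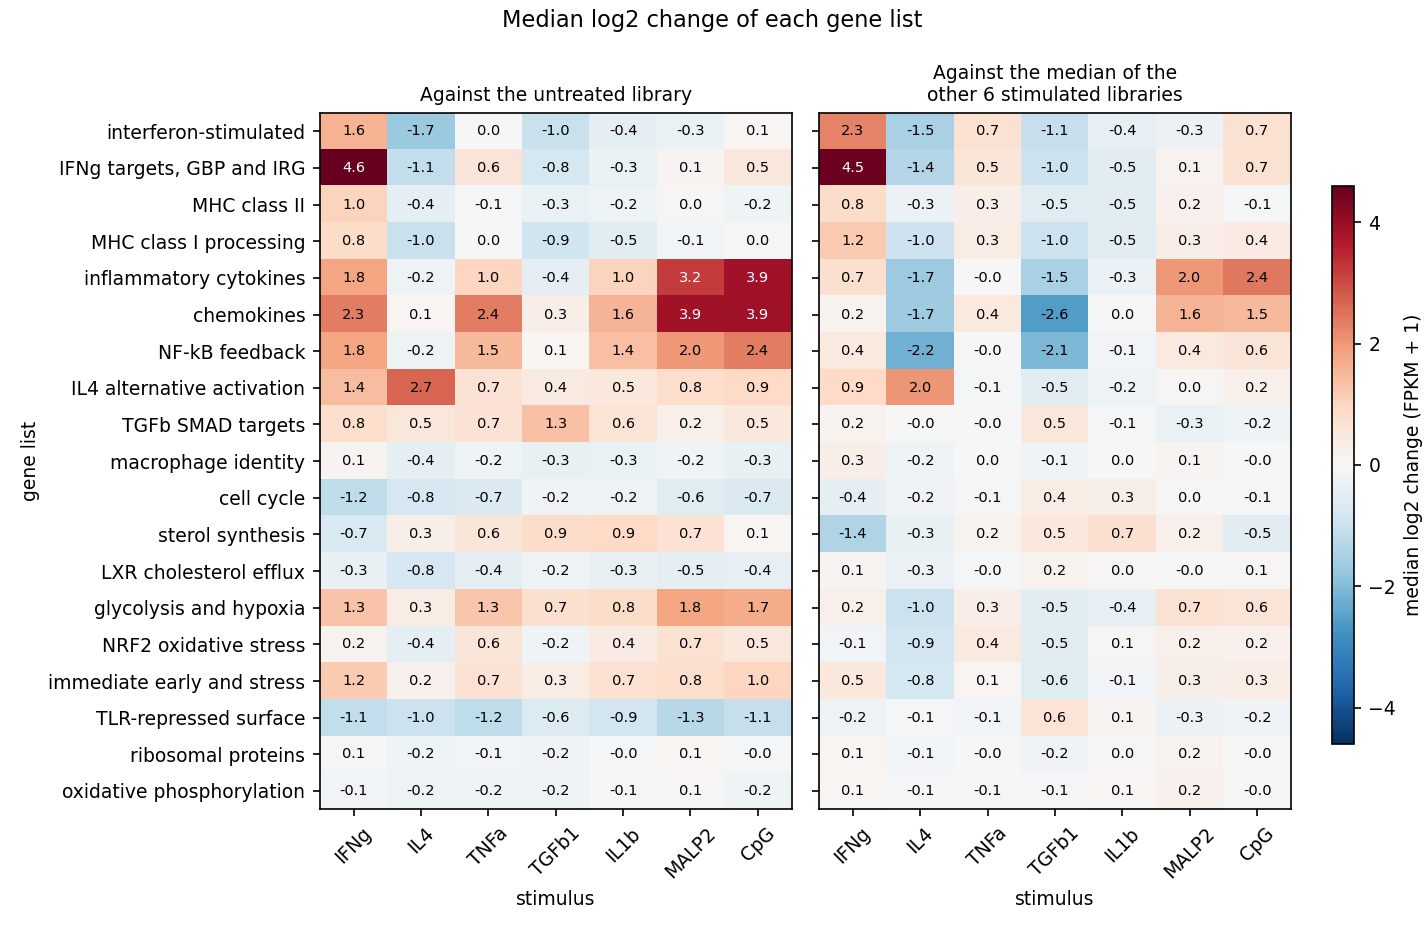
Median log2 change of FPKM + 1 for 19 gene lists (lines) in each of the 7 stimuli (columns), against the untreated library (left) and against the median of the other 6 stimulated libraries (right); red is higher and blue lower. IFNg targets are at 4.59 after IFNg and interferon-stimulated genes at -1.71 after IL4, and cytokine genes at 3.23 and 3.86 after MALP2 and CpG.

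Stimulated libraries were next set against each other, which leaves the untreated library out of the difference. MALP2 and CpG gave the closest pair, with 228 of 12075 genes at least 2-fold apart, 140 of them higher after CpG. The interleukin 12 subunit gene Il12b (59.9 against 5.35 FPKM), the anti-inflammatory Il10 (76.8 against 18.5 FPKM) and its relative Il19 (7.4 against 1.69 FPKM) were higher after CpG, and Rasal1 (2.76 against 0.124 FPKM) and Hpn (5.8 against 2.27 FPKM) after MALP2. Between TNFa and IL1b 360 genes were apart. Ccl22 (36.5 against 4.08 FPKM), Ccl5 (128 against 19.9 FPKM), the complement gene Cfb (15.4 against 1.82 FPKM) and the membrane protease Mmp14 (173 against 34.1 FPKM) were higher after TNFa. Higher after IL1b were the transporter Slco2b1 (18.1 against 2.23 FPKM), Cxcl1 (30.5 against 7.35 FPKM) and the replication helicase gene Mcm2 (18.4 against 4.14 FPKM). IFNg and IL4 differed in 2561 of 12631 genes, among them Cxcl10 (7589 against 8.93 FPKM), Gbp2b (702 against 1.15 FPKM) and Calhm6 (310.2 against 0.622 FPKM) on the IFNg side, and Arg1 (1766 against 4.49 FPKM), Retnla (37.5 against 0.154 FPKM) and Tmem26 (58.8 against 0.115 FPKM) on the IL4 side. MALP2 and TNFa differed in 580 genes, with Saa3 (4805 against 188 FPKM), Ccl3 (2394 against 112 FPKM) and Nos2 (41.7 against 1.09 FPKM) higher after MALP2, and Rgs2 (35.6 against 2.51 FPKM), Cxcr4 (38.9 against 4.23 FPKM) and the protease gene Plau (189.9 against 29.6 FPKM) after TNFa. These genes were chosen after their values were seen, as protein-coding genes whose bounds lay apart, because the planned choice by size took 39 of 40 genes that do not code for protein and 39 listed at 0 in the lower library. Such genes numbered 27 higher after CpG and 2 after MALP2, and 78 higher after TNFa and 36 after IL1b. They numbered 768 higher after IFNg and 574 after IL4, and 121 higher after MALP2 and 85 after TNFa. The rest of the genes counted as apart did not code for protein, had no unique symbol or had overlapping bounds. The values come from tables scaled separately and joined through the untreated values.

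Across 13467 genes the log2 changes of MALP2 and CpG against the untreated library had a Pearson correlation of 0.86 and a Spearman correlation of 0.91, those of TNFa and IL1b 0.83 and 0.89, and those of IFNg and IL4 0.47 and 0.50. Genes are not independent replicates, and all 7 comparisons share 1 untreated library. Simulated unchanged libraries against it gave 0.49 and 0.47. That level is set by the shared control with equal noise in each library, whatever the size of the noise. Correlations near it, as for IFNg and IL4, thus cannot tell a shared response from the shared control. The covariance was 0.93 for MALP2 and CpG and 0.553 for IFNg and IL4, against 0.154 simulated. MALP2 and CpG shared 967 higher genes, 80.9% of the shorter list, where independent lists would share 107. IFNg and IL4 shared 421 against 129, or 33.1%. Simulated libraries had 211 higher genes each and shared 85.2 of them, and lists of that length give no measure for the longer ones. Their noise came from the difference of TNFa and IL1b, which are different agents with 360 genes apart. The part of the shared control, which is 1 library, was not separated. With each change taken against the other 6 stimulated libraries the correlation was 0.42 for MALP2 and CpG, -0.16 for IFNg and IL4, and 0.35 for IL4 and TGFb1.

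Of 13467 genes, 1394 were higher in exactly 1 stimulated library and 194 in all 7, while 886 were lower in exactly 1 and 374 in all 7. Genes higher in 1 library came most from IFNg (519) and IL4 (415) and least from IL1b (34). Among protein-coding genes higher in all 7, chosen after their values were seen, Gpr84 was 3.94 FPKM untreated and 32.6 to 938 FPKM after stimulation, Id1 1.08 and 47.5 to 77.9, Ch25h 3.24 and 34.1 to 532, and Adora2b, an adenosine receptor gene, 1.12 and 5.98 to 108. Among protein-coding genes lower in all 7, Arhgap19 was 69.6 FPKM untreated and 1.85 to 10.5 after stimulation, Slc26a11 45.9 and 0.699 to 6.95, Tcp11l2 43.3 and 0.793 to 3.61, and Lrrc14b 21.2 and 0.192 to 0.44. The largest falls in all 7 were in short RNA genes such as Scarna9, at 1106 FPKM untreated and listed at 0 in every stimulated library. The largest rise was in the small nucleolar RNA gene Gm23455, listed at 0 untreated and 32.1 to 247 FPKM after stimulation. For the pairs above, the 39 genes taken by size that do not code for protein all had overlapping bounds. Changes of such short RNA genes are therefore uncertain. The untreated library was the farthest from the rest: it differed from the stimulated libraries in 2011 to 2970 genes (median 2612), while the median distance of each stimulated library was 773 to 1917 genes. Every comparison with the untreated library above includes the 568 genes that differ in all 7, of which 470 code for protein.

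**Figure D3:**
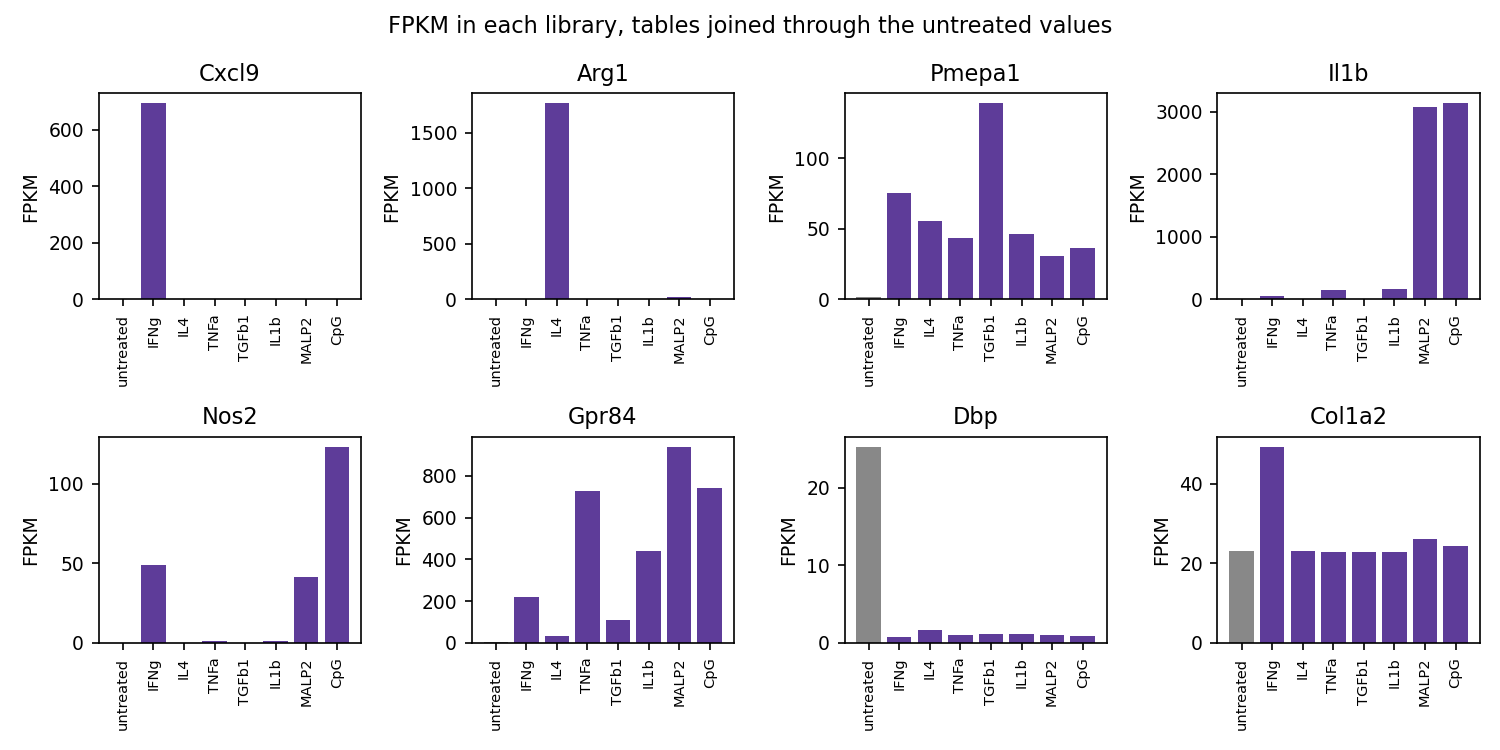
FPKM (vertical axes, from 0) of 8 genes in each of the 8 libraries, 1 bar per library, with the untreated library in grey and tables joined through the untreated values. Cxcl9 is 694 FPKM after IFNg, Arg1 1766 after IL4, Pmepa1 139 after TGFb1, and Col1a2 49.2 after IFNg against 23.2 untreated.

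**Figure D4:**
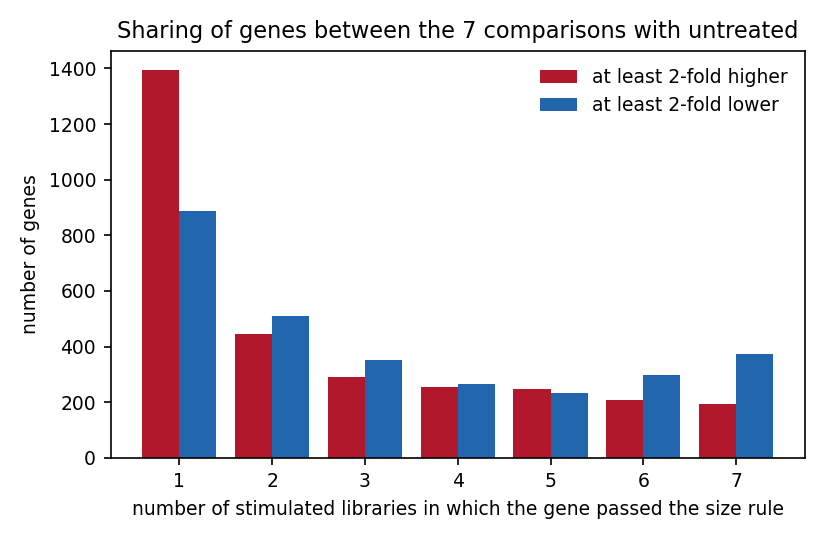
Number of genes (vertical axis) at least 2-fold higher (red) or lower (blue) than the untreated library in exactly 1 to 7 of the stimulated libraries (horizontal axis). The counts fall from 1394 to 194 for higher genes and, for lower genes, stand at 886, 233 and 374 for 1, 5 and 7 libraries.

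Of 43 ribosomal protein genes none was 2-fold higher or lower in any comparison (medians -0.19 to 0.082), and of the oxidative phosphorylation genes only the cytochrome c gene Cycs passed, in each stimulus (for example 12.6 against 3.29 FPKM after IFNg; list medians -0.23 to 0.061). Genes known to be repressed by Toll-like receptor ligands had medians of -1.29 to -0.65, and Il16 was 1.04 against 23.8 FPKM after IFNg and 2.27 against 25.5 FPKM after IL1b. Set against the other 6 stimulated libraries, these medians were -0.28 for MALP2, -0.15 for CpG, -0.22 for IFNg, -0.12 for TNFa and -0.061 for IL4. Immediate early and stress genes had medians of 0.19 to 1.2, with Myc highest after IL4. Glycolysis and hypoxia genes had medians of 0.34 to 1.83, highest after MALP2 and lowest after IL4. Against the other 6 stimulated libraries the immediate early median of IL4 turned to -0.82, the glycolysis medians of TGFb1 and IL1b to -0.51 and -0.36, their immediate early medians to -0.56 and -0.13, and their medians of Toll-repressed genes to 0.64 and 0.14.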

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

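No paired analysis was possible because each group holds 1 library. The comparison with the other 6 stimulated libraries and the restriction to protein-coding genes were chosen after seeing the data. A pseudocount of 0.1, a floor of 5 FPKM, centring on the median gene and protein-coding genes alone left all 14 counts within 1.5 times of those reported, although centring turned the balance to more higher than lower genes in all 7 comparisons (1526 and 1389 for IFNg). Centring moved the median gene by up to -0.10 (CpG). Dropping the floor cannot change a count, since with 1 added a gene under 1 FPKM in both libraries cannot differ 2-fold. The authors' call lowered the lower genes after IFNg to 1073 and the higher genes after MALP2 to 806, and 8 of 21 overlaps by more than 1.5 times, since it asks for more. With the other 6 stimulated libraries as the reference the higher and lower counts were 624 and 710 for IL4, 203 and 94 for TNFa, 457 and 487 for TGFb1, 154 and 122 for IL1b, 405 and 174 for MALP2, and 465 and 96 for CpG, and the lower count for IFNg was 409. Only the 960 higher genes of IFNg stayed within 1.5 times. Of the genes past 2-fold on that reference, 658 higher and 179 lower ones for IFNg also passed the rule against the untreated library. For IL4 these were 369 and 331, for TNFa 153 and 43, and for TGFb1 222 and 164. For IL1b they were 75 and 22, for MALP2 298 and 100, and for CpG 359 and 52. Correlations moved by less than 0.1 with the pseudocount of 0.1, the floor of 5, no floor and centring. Against the other 6 stimulated libraries all 21 moved by more, to between -0.52 and 0.42; there each library is part of the reference of the others, which by construction lowers a correlation. Of the named gene values 89 of 793 moved beyond the authors' bounds with a pseudocount of 0.1, and none changed sign. A list median was counted as moved when it shifted by the standard deviation of the random list medians or more. By this measure 32 of 186 moved with that pseudocount, 40 of 182 with the floor of 5 and 46 of 186 without a floor. With members that no other list holds 35 of 185 moved, with protein-coding genes 5 of 186 and with centring 0 of 186. Against the other 6 stimulated libraries 118 of 186 moved, where 25 more that changed sign are counted apart.

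Against the other 6 stimulated libraries 64 of 186 medians of the fixed lists changed sign. Of these, 39 had lain within the range of random lists, among them chemokine genes after TGFb1 (-2.58) and IL4 (-1.65), NF-kB genes after TGFb1 (-2.05), immediate early genes after IL4 (-0.82) and sterol synthesis genes after CpG (-0.52) and IL4 (-0.34). The other 25 had lain beyond it. For TNFa these were cytokine genes (-0.014), NF-kB genes (-0.012), alternative activation genes (-0.054) and SMAD genes (-0.029). For IL1b they were cytokine (-0.28), NF-kB (-0.14), alternative activation (-0.25), SMAD (-0.094), macrophage (0.0096), glycolysis (-0.36), immediate early (-0.13), Toll-repressed (0.14) and B cell genes (0.034). For TGFb1 they were alternative activation (-0.48), glycolysis (-0.51), immediate early (-0.56), Toll-repressed (0.64) and B cell genes (0.11). For IL4 they were SMAD (-0.033), glycolysis (-1.0) and B cell genes (0.27), for MALP2 SMAD (-0.31), cell cycle (0.032) and B cell genes (0.012), and for CpG SMAD genes (-0.19). The B cell median after TGFb1 was 0.000149 without a floor, since members near 0 FPKM then enter it. Outside the fixed lists, the added FOXO and starvation list also turned, for IL4 (0.18), TGFb1 (0.45), IL1b (0.013) and CpG (0.016), and the added ERK and growth factor list for IFNg (-0.36), TGFb1 (-0.24), MALP2 (-0.14) and CpG (-0.23). The added clock list turned for TNFa (0.16), TGFb1 (0.26), IL1b (0.10) and CpG (0.058), and the added stromal list for IL4 (-0.18), TNFa (-0.12), IL1b (-0.043) and MALP2 (-0.099). This reference holds the other agents, so a change common to several of them cancels; the cause was not tested further. The unknown depth limits genes of low FPKM most, and the IFNg library more than the others.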

Other observations

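The tests on depth, B or plasma cells, and neutrophils or stromal cells in the untreated library, on short RNA genes and on the scaling of the IFNg table were chosen only after the result was seen, and the 4 added gene lists were written after the first results. Macrophage identity genes had medians of -0.41 to 0.12, while single members differed more. The mannose receptor gene Mrc1 was 902 against 99.9 FPKM after IL4, the scavenger receptor genes Marco and Msr1 were 18.7 against 0.0638 FPKM and 168 against 16.9 FPKM after MALP2, and Mertk, a receptor for dying cells, was 1.15 against 22.7 FPKM after MALP2 and 1.71 against 23.1 FPKM after TNFa. The transcription factor Batf3, on the dendritic list, was 36.4 against 2.48 FPKM after IL4 and was listed at 0 after TGFb1 (list medians -0.71 to 0.41). The integrin gene Itgb3, on the osteoclast list, was 103 against 4.97 FPKM after IL4, and the phosphatase gene Acp5 38.2 against 6.63 FPKM after MALP2 (list medians -1.04 to 0.31). Lck, a T cell kinase gene, was 0.906 FPKM untreated, 11.2 FPKM after IFNg and 0.369 to 1.52 FPKM in the other 6, while Cd3e was 0.024 FPKM after IFNg. Endothelial genes had medians of -0.74 to 0.071, with Pecam1 at 11 against 0.487 FPKM after IL4. Among mast cell and eosinophil genes Hdc was 6.38 against 0.596 FPKM after IFNg. The list median there was 1.52, but only 3 of its 15 genes were measured, 2 higher and 1 lower.

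Among genes of cholesterol export, the cholesterol exporter Abcg1 was 5.39 against 98.9 FPKM after TNFa and 4.28 against 97.1 FPKM after MALP2, and its relative Abca1 was 4.4 against 42.7 FPKM after IL4. Their regulator Nr1h3, the liver X receptor gene, was 47.6 against 7.96 FPKM after TNFa and 46 against 7.81 FPKM after MALP2 (list medians -0.76 to -0.21, and -0.27 to 0.16 against the other 6 stimulated libraries). NRF2 and stress genes had medians of -0.44 to 0.71, and -0.89 (IL4) to 0.43 (TNFa) against the other 6 stimulated libraries. Among them the metallothionein gene Mt2 was 437 against 23.8 FPKM after IFNg and 653 against 24.8 FPKM after CpG. Haem oxygenase Hmox1 was 1064 against 288 FPKM after TNFa and 136 against 299 FPKM after IL4, the last with overlapping bounds. Nfe2l2, which encodes NRF2, was 35.1 against 207 FPKM after IL4.

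The 568 genes that differed from the untreated library in all 7 stimulated libraries include Gpr84, Id1, Arhgap19 and Tcp11l2, so the untreated culture may differ by more than the lack of an agent. Counting noise as the main source is argued against, since MALP2 and CpG, both shallower than the untreated library, differed in 228 genes. Neutrophils or stromal cells in the untreated library are argued against as the main source too. Of their 13 genes at 3 FPKM or more (6 neutrophil and 7 stromal), 0% were lower in all 7. A small share of neutrophils is not excluded by this, since their list median was below 0 in every comparison (-0.95 to -0.029). For B or plasma cells in the untreated library the measures part. The median of their 14 listed genes was 0.102 FPKM there, which speaks against them. By the measure used for neutrophils, however, 3 of their 4 genes at 3 FPKM or more were lower in all 7 (Ighm, Blnk and Cd79b). B or plasma cells are therefore not settled here. Length or GC bias stays open, with 77.3% of 542 genes past 2-fold after its removal, between the bounds set beforehand, as does a shift of the circadian clock, whose output genes lay beyond the matched lists in 5 of 7 comparisons (medians -1.31 to -0.50, and -0.38 to 0.26 against the other 6). A starved untreated culture and a growth signal in the stimulated ones remain candidate explanations that were not separated from each other. FOXO and starvation genes were below the matched lists in 7 of 7 comparisons (medians -1.32 to -0.82, and -0.16 to 0.45 against the other 6). ERK and growth factor genes were above them in 7 of 7 (medians 1.19 to 1.85, and -0.36 to 0.64). All 7 comparisons share 1 untreated library, so these counts, like that of the clock genes, are not independent. Other lists also passed in 7 of 7. Toll-repressed and B cell genes were below the matched lists, and glycolysis, SMAD and alternative activation genes above them. Passing in 7 of 7 thus does not single out either explanation. The labels mention feeding with fresh medium but not when relative to stimulation, and other cell types and a response common to all 7 agents, the biological alternative, were not tested.

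Genes past the 2-fold rule in exactly 1 stimulated library, many of them after IFNg and IL4, could in part be noise of short RNA genes. Of 1795 such genes with a known length, 6.18% had a longest transcript under 200 bases, against 4.24% of the genes that differ in all 7, which argues against short RNAs as the main source.

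Stromal genes such as Col1a2, Sparc and Bgn were about 2-fold higher in the IFNg library than in the other 6. A uniform scaling of that table is argued against, since the median log2 change of all expressed genes was -0.092. That median cannot speak to an effect confined to some genes. In the IFNg library 1 read was also worth 2.04 times as much FPKM as in the untreated one. Whether the stromal rise is tied to this lower depth was not tested for the IFNg culture. More stromal cells in that culture are a candidate explanation, and whether any are L929 fibroblasts left from the conditioned medium was not tested: a second list of stromal genes, written before its values were seen, had a median log2 of 0.72 against the other 6 (25 genes, quartiles 0.60 and 0.93, 24 above 0, Cav2 at -1.51). Its most abundant members were Lamc1 at 44.6 FPKM against 16.8 to 52.1 and Timp3 at 28.8 against 9.84 to 17.4, and 18 members were at 1 FPKM or more in the untreated library and 0 were on another list. A response of these genes to IFNg itself was not tested and stays open.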
